A study of Mus musculus with 19 samples.

How the data were processed

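Kidney RNA was measured by sequencing in 19 libraries from male C57BL/6 mice, an inbred laboratory strain. Per the labels, the libraries form 4 groups: 5 of sham-operated kidneys (sham), 5 of kidneys taken after ischemia-reperfusion (IR), 5 labelled IRLac and 4 labelled IRLacz. Ischemia-reperfusion stops the blood flow to the kidney for a time and then restores it. The treated mice had been gavaged for 4 weeks with a Lactobacillus strain before the injury, and kidneys were taken on day 5 after it. No gavage is given for the sham and IR groups. The design text abbreviates Lactobacillus casei Zhang in a way that matches IRLacz. IRLac was taken as Lactobacillus acidophilus by elimination, because its abbreviation in the design text differs by a letter. Groups and replicate numbers came from the sample titles. The labels do not say outright that each library came from its own mouse, so a p-value measures the spread between these libraries.

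The authors deposited 1 table of FPKM values (fragment counts scaled by gene length and by sequencing depth), with 2 decimals and a column for each library. The submitters' processing notes name HISAT, StringTie 1.0.4 and the mouse build mm9, without saying what each was used for. RNA was extracted with Trizol and checked on a Bioanalyzer, per the labels' protocols, and libraries followed a standard Illumina protocol. The annotation, the handling of reads shared between genes, strand and any filter are not given in the sources used here. A second deposited table by the authors lists transcription factors with the percent identity of each gene's protein to its best database match. It was used for family names at an identity of at least 95 percent, and another table of the same kind was not used here.

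The FPKM table held 19287 entries. Of these, 18238 had a gene ID found in a RefSeq table of assembly GRCm38, which was used for names only, because the deposited values were made on another build. No coordinates were used. A further 933 entries were loci with an assembly identifier and no gene name, and 116 had an ID without a match; both kinds are named by the identifier in the file. FPKM totals ranged from 545590 to 584798 per library, which is not a measure of depth, and read depth is not stated. The low values of 110 genes moved in steps. Of 442 values of 2 to 5 steps, 62.22% lay within 0.1 step of a whole number, against 20% with no steps, and the step sizes put relative depth between 0.976 and 1.035. These genes were selected after the values had been looked at. Only values close to the lowest of each gene set the relative depth, so a library of much lower depth could be missed. In 27 entries a library was listed at exactly 0 while the median over libraries was above 5 FPKM, so a 0 can be a failed estimate. Correlations between libraries of a group ranged from 0.9604 to 0.9929 on the log2(FPKM + 1) scale, with no pair alike enough to be 1 library deposited more than once.

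Because FPKM values are not counts, no count model was used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 19 libraries in 1 model, which leaves 15 residual degrees of freedom. Entries with at least 1 FPKM in at least 4 libraries were tested, 13594 in all. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. The limma steps were tested on simulated data with 200 genes changed on the log2(FPKM + 1) scale. Each gene was drawn on its own, without the variation that genes of a library share. The rates below therefore test the steps and need not hold for the real libraries. For IRLacz against IR, over 13594 genes, 77.6% of genes changed 1.5-fold were recovered, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 false calls among 189. For IRLac against IR the recovered shares were 77.6%, 94% and 100%, with 14 false calls among 195.

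The groups, the tests, 36 gene lists, the rule for named genes and all alternatives but the last 2 given here were fixed before the data were examined. The lists held 889 genes, of which 19 were not found under the names used, and 30 lists had at least 5 tested members. Too few members were tested for lists of B and plasma cells (3), neutrophils (4), adipose tissue (2), adrenal gland (2), skeletal muscle (4) and mitochondrially encoded RNA (0). Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Each list also received a score per library, the mean of log2(FPKM + 1) over tested members, and scores were compared between groups with a two-sided exact permutation test, adjusted over the 30 lists. The smallest p this test can give is 0.00794. Named genes were a fixed set of 12, up to 2 members with the smallest adjusted p from each of the 10 lists with the smallest camera p, and the 4 largest rises and 4 largest falls among called genes with no overlap between groups and a mean of at least 5 FPKM in the higher group. Where no gene passed that last part, the 3 smallest p-values in each direction were taken. Some genes that the rule names are not given here, while counts over named genes include them.

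A position was computed for each library by projecting it on the line from the sham mean (0%) to the IR mean (100%), over the genes called in IR against sham. The line is built from sham and IR, so those groups lie near its ends by construction. The covariance across genes between comparisons that share the IR libraries was computed with the 5 IR libraries split in all 20 ordered ways, and set beside 1000 simulated draws of unchanged groups. Alternatives changed the pseudocount, the filter, the scaling (to a common total as TPM, by median ratio, or by quantiles), the trend, robust estimation, library weights, the libraries in the model, a replicate block and the inter-gene correlation, and left out each replicate in turn. Leaving out the 2 injured libraries nearest to sham and adding the position as a covariate were chosen after seeing the data.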

Results

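Kidney RNA was profiled in sham, IR, IRLac and IRLacz libraries (n = 5, 5, 5 and 4). Between 11988 and 12156 entries reached 1 FPKM in the sham libraries, and between 12750 and 13283 in the 14 libraries of injured kidneys. Estimated relative depth ranged from 0.976 to 1.035, by an estimate that could miss a library of much lower depth.

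The comparison of IR with sham asked what the injury changed in the kidney at day 5. Havcr1 (gene ID 171283), which encodes kidney injury molecule 1, was at 487.8 ± 53.3 FPKM (SD, n = 5) in IR and at 1.218 ± 0.284 FPKM (n = 5) in sham, a log2 difference of 7.79 (SE 0.31, limma adjusted p = 9.6e-12). Lcn2 (16819), which encodes the iron-carrier-binding protein lipocalin 2, rose from 3.752 ± 0.993 to 386.6 ± 106 FPKM. Serpina10 rose from 0.928 ± 0.326 to 81.69 ± 11.4 FPKM, and the complement gene C3 from 4.634 ± 0.583 to 212.2 ± 70.7 FPKM. The largest falls under the naming rule were those of Serpina1d (170.5 ± 21.8 to 6.736 ± 9.41 FPKM), the organic anion transporter gene Slc22a7 (209.9 ± 32 to 11.03 ± 12.2 FPKM), Egf (481.4 ± 52.4 to 35.4 ± 23.8 FPKM) and Pvalb (33.53 ± 2.74 to 1.868 ± 2.45 FPKM), with adjusted p from 1.7e-06 to 0.00015. Serpina1d belongs to a family of near-identical copies, so its level is uncertain.

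Genes of the tubule moved in opposite directions with injury. All 35 tubular injury genes rose, with a median log2 difference of 2.88. In the proximal tubule list 42 of 46 genes fell and 2 rose (median -1.24), among them the phosphate transporter gene Slc34a1 (2755 ± 152 to 1154 ± 207 FPKM), G6pc, the last enzyme of glucose release (333 ± 59.6 to 43.28 ± 11.4 FPKM), and Dpys (14.64 ± 3.08 to 2.728 ± 0.929 FPKM). In the thick limb and distal tubule list 16 of 19 genes fell (median -0.92), including Trpm6 (4.19 ± 0.709 to 1.906 ± 0.221 FPKM). Umod, the thick limb gene for uromodulin, was at 1194 ± 225 FPKM in IR and 1749 ± 273 FPKM in sham and did not pass (adjusted p = 0.062, or 0.0428 without sham replicate 1). In the collecting duct list 11 of 20 genes fell and 1 rose (median -0.461).

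Matrix, immune and cell cycle genes rose with injury. All 35 fibroblast and matrix genes were called higher (median 2.39), including the collagen genes Col1a1 (12.9 ± 1.48 to 192.5 ± 23.2 FPKM) and Col3a1 (11.58 ± 1.85 to 287.7 ± 23.7 FPKM) and fibronectin, Fn1 (6.154 ± 0.935 to 63.61 ± 8.22 FPKM). All 34 macrophage and monocyte genes rose (median 3.19), including Lyz2 (24.94 ± 4.83 to 648.5 ± 127 FPKM), Cx3cr1 (1.822 ± 0.308 to 17.05 ± 1.44 FPKM) and Adgre1 (1.844 ± 0.473 to 20.16 ± 1.55 FPKM). Of 45 inflammatory mediator genes 43 rose (median 2.1), among them Ccl2 (0.89 ± 0.603 to 54.77 ± 9.67 FPKM), Cx3cl1 (30.64 ± 1.94 to 85.93 ± 7.28 FPKM), Osmr (2.2 ± 0.435 to 15.64 ± 1.44 FPKM), Il1b (0.786 ± 0.41 to 3.724 ± 0.481 FPKM) and Tnf (0.172 ± 0.118 to 1.14 ± 0.3 FPKM). The lists of genes associated with M1 and M2 macrophage states had 9 of 9 and 12 of 14 members higher, and the T and NK cell list 15 of 17. The interferon response list had 38 of 39 members higher, and the complement and acute phase list 18 of 20 with 1 lower. All 40 cell cycle genes rose (median 1.97), including Rrm2, a subunit of ribonucleotide reductase (1.71 ± 0.199 to 16.6 ± 3.33 FPKM), and Kif20a (0.42 ± 0.148 to 4.99 ± 0.681 FPKM).

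Most genes of fatty acid oxidation, oxidative phosphorylation and the citrate cycle fell. In the fatty acid oxidation list 38 of 42 genes fell and 1 rose (median -0.943), including Acad12 (28.61 ± 0.863 to 9.772 ± 1.63 FPKM), Acsl1 (69.69 ± 4.1 to 31.96 ± 4.82 FPKM) and Ppargc1a, a coactivator of mitochondrial genes (10.3 ± 1.12 to 5.872 ± 0.942 FPKM). In the oxidative phosphorylation list 47 of 48 genes fell (median -0.55), including Sdhc (319.4 ± 7.78 to 185.3 ± 11.1 FPKM) and Sdha (321.8 ± 12.1 to 174.5 ± 20.4 FPKM). All 21 genes of the citrate cycle list fell (median -0.732), including Idh3g (235.1 ± 4.15 to 141.4 ± 9.14 FPKM). The list also holds the kinase gene Pdk2, which encodes no enzyme of the cycle itself (134.5 ± 8.85 to 63.48 ± 10.4 FPKM). Of 33 genes of nicotinamide and NAD metabolism 17 fell and 9 rose. Nnmt, which methylates nicotinamide, rose from 0.916 ± 0.746 to 11.13 ± 1.62 FPKM. Nampt was at 23.29 ± 3.61 against 25.69 ± 1.29 FPKM (adjusted p = 0.16, or 0.0448 without IR replicate 4). Of 21 genes of short-chain fatty acid handling 17 fell and 3 rose.

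Among the other lists, 20 of 23 p53 and apoptosis genes, 13 of 21 endoplasmic reticulum stress genes and 14 of 18 immediate early and heat shock genes rose, while 16 of 29 antioxidant genes fell and 8 rose. Glycolysis genes were divided (7 higher and 6 lower of 20), as were podocyte genes (6 and 3 of 14), endothelial genes (8 and 4 of 18), clock genes (6 and 6 of 18) and urothelial genes (3 and 1 of 9). The median sign of these 5 lists changed under at least 1 scaling, for glycolysis as TPM and for the other 4 under median-ratio and quantile scaling. Camera's direction was down for all 5, against positive medians in 4 of them. Glycolysis had a mean of 0.271 and a median of -0.0124. The glycolysis and podocyte scores were higher in IR, by 0.271 and 0.276 (exact permutation adjusted p = 0.00952 for both). Ribosomal protein genes rose in 37 of 38 cases, histone genes fell in 5 of 7, and red blood cell genes, which include near-identical globin copies, fell in 4 of 5. Adjusted over the list alone, the counts were the same in all lists except the clock genes (5 higher and 6 lower) and the ribosomal protein genes (38 higher).

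In limma, 7747 entries were higher and 2529 lower in IR than in sham, of 13594 tested, and 10481 had an unadjusted p under 0.05. The median over all entries was 0.29 on the log2 scale. With median-ratio scaling, which brought that shift to 0.0111, 4830 were higher and 4721 lower, and with quantile scaling 4222 and 5294. Camera called 23 of 30 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.229. Scores per library differed in 27 of 30 lists by the exact permutation test, 25 of them with adjusted p = 0.00952, the value that the smallest possible p gave.

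**Figure D1:**
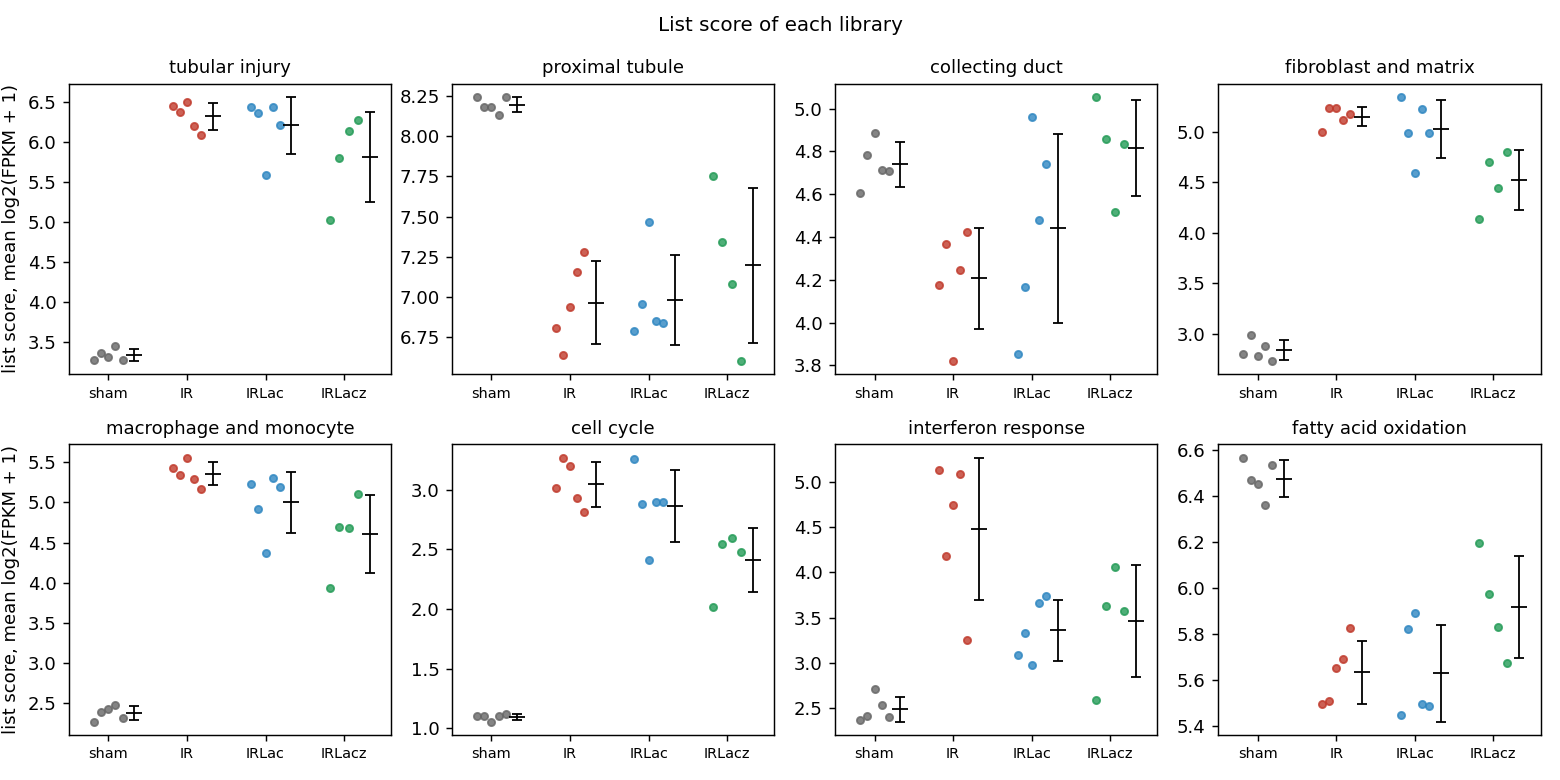
Score of 8 gene lists in each library, as the mean of log2(FPKM + 1) over the list's tested members, by group (sham n = 5, IR n = 5, IRLac n = 5, IRLacz n = 4), with the group mean and SD as a bar beside the points. The tubular injury score was 3.335 ± 0.073 in sham and 6.32 ± 0.173 in IR, and the fibroblast and matrix score fell from 5.148 ± 0.097 in IR to 4.521 ± 0.297 in IRLacz.

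On the line from sham (0%) to IR (100%), IRLacz libraries lay at 77% ± 22.2 (n = 4) and IRLac libraries at 91.5% ± 14.1 (n = 5), against 99.8% ± 8 (n = 5) in IR. No p-value is given for these positions, because the line is built from the IR libraries themselves. IRLacz replicate 1 lay at 46% and IRLac replicate 3 at 67%, while the other IRLacz libraries lay between 77.5% and 97.5%. The first principal component held 75.5% of the variance and parted sham from the injured kidneys. IRLacz lay below IR on it by a difference of -21.2 that did not pass (exact permutation p = 0.0556). On the second, with 5.5%, IRLacz lay 25.5 units below IR (difference -25.5, exact permutation p = 0.00794).

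**Figure D2:**
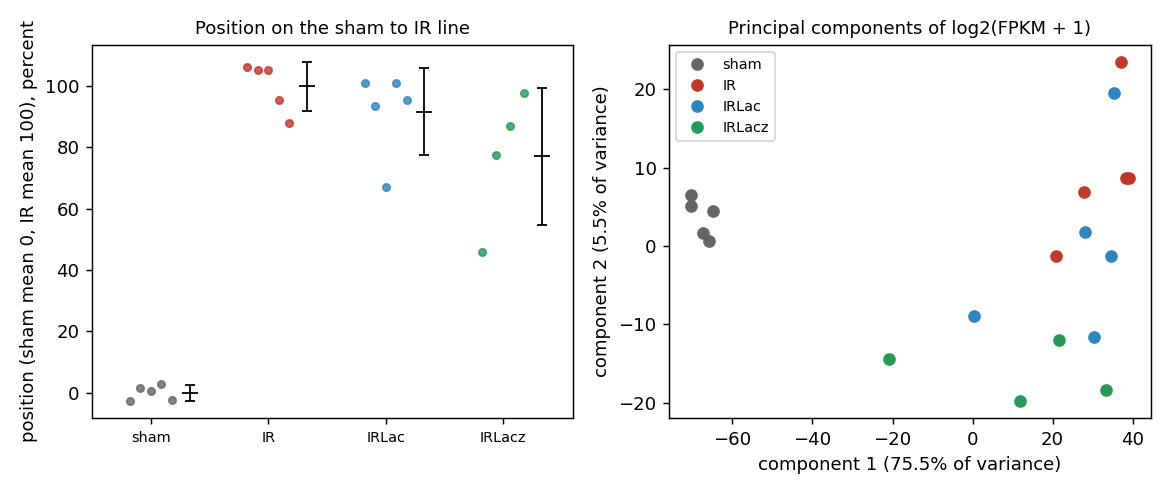
Left, position of each library on the line from the sham mean to the IR mean, in percent, with the group mean and SD beside the points. Right, the first and second principal components of log2(FPKM + 1), with 75.5% and 5.5% of the variance; IRLacz replicate 1 lies at 46% on the left and between sham and the other injured libraries on the right.

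The comparison of IRLacz with IR asked how injured kidneys differed after 4 weeks of gavage with Lactobacillus casei Zhang. No gavage is given for IR, so the strain cannot be told apart from the gavage itself here. Members of the fibroblast and matrix list were lower. Acta2 (gene ID 11475), which encodes smooth muscle actin, was at 41.19 ± 5.27 FPKM (SD, n = 4) in IRLacz and 98.32 ± 15.2 FPKM (n = 5) in IR, a log2 difference of -1.23 (SE 0.21, limma adjusted p = 0.0049). Col3a1 fell from 287.7 ± 23.7 to 157.8 ± 32.1 FPKM and Col1a1 from 192.5 ± 23.2 to 97.86 ± 29.3 FPKM (adjusted p = 0.0084). The chemokine gene Ccl8 (20307) fell from 20.28 ± 5.69 to 4.055 ± 1.43 FPKM, a log2 difference of -2.09 (adjusted p = 0.0039), and Ccl7 from 11.22 ± 4 to 3.458 ± 1.79 FPKM. Ppargc1a was higher, at 10.49 ± 1.53 against 5.872 ± 0.942 FPKM (adjusted p = 0.0063), and the sham level was 10.3 ± 1.12 FPKM.

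Of 35 fibroblast and matrix genes 24 were lower in IRLacz than in IR, of 34 macrophage and monocyte genes 21, of 40 cell cycle genes 30 and of 45 inflammatory mediator genes 17, and none of these lists had a member called higher by limma. Adjusted over the list alone, the counts were 28, 29, 38 and 22. Among them, the Fc receptor gene Fcgr1 fell from 16.12 ± 4.92 to 6.188 ± 2.65 FPKM, Clec4n from 10.33 ± 2.38 to 4.245 ± 1.16 FPKM, the mitotic kinase gene Plk1 from 9.126 ± 2.12 to 3.99 ± 0.669 FPKM and Rrm2 from 16.6 ± 3.33 to 9.445 ± 1.45 FPKM. Adgre1 (12.48 ± 4.58 against 20.16 ± 1.55 FPKM, adjusted p = 0.03) and Il1b (2.198 ± 0.349 against 3.724 ± 0.481 FPKM, adjusted p = 0.041) were lower. Ccl2, at 27.64 ± 12.3 against 54.77 ± 9.67 FPKM, did not pass (adjusted p = 0.052). Neither did Tnf, at 0.7675 ± 0.41 against 1.14 ± 0.3 FPKM (adjusted p = 0.17). Gpnmb fell from 14.5 ± 8.23 to 2.5 ± 1.85 FPKM.

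In the tubular injury list 12 of 35 genes were lower (15 adjusted over the list alone), including Plaur, the urokinase receptor gene (35.44 ± 6.62 to 15.82 ± 4.64 FPKM). Havcr1 (372.6 ± 189 against 487.8 ± 53.3 FPKM, adjusted p = 0.25) and Lcn2 (257.7 ± 127 against 386.6 ± 106 FPKM, adjusted p = 0.15) did not pass. In the endoplasmic reticulum stress list 10 of 21 genes were lower (11 adjusted over the list alone), including the chaperone gene Hspa5 (311.9 ± 74 to 161.7 ± 24.2 FPKM) and Creld2 (41.08 ± 11.6 to 21.74 ± 0.323 FPKM). In IRLacz both lay below sham. Hspa5 was at 139.88 to 185.5 FPKM against 192.24 to 273.25 FPKM in sham, and Creld2 at 21.34 to 22.1 against 27.12 to 39.24 FPKM. The score of the whole list was 4.904 in IRLacz and 4.764 in sham. The interferon response list had 21 of 39 genes lower (28 adjusted over the list alone), including Bst2 (263.3 ± 136 to 66.74 ± 24 FPKM) and Oas3 (3.666 ± 2.12 to 0.705 ± 0.464 FPKM). Its score difference of -1.02 did not pass (exact permutation p = 0.0873, adjusted p = 0.187). In IR replicate 5 Bst2 was at 70.09 FPKM and Oas3 at 0.61 FPKM. The other IR libraries had 176.62 to 381.48 FPKM and 2.42 to 5.84 FPKM. Rps18 fell from 356.6 ± 96.6 to 98.66 ± 53.1 FPKM, a value that is uncertain because near-identical copies of ribosomal protein genes share reads. It was the 1 of 38 ribosomal protein genes called.

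Among lists of the distal nephron and of fatty acid oxidation, the collecting duct score passed, while those of the thick limb and distal tubule (0.749, exact permutation adjusted p = 0.119) and of fatty acid oxidation (0.285, adjusted p = 0.152) did not. In the collecting duct list 8 of 20 genes were higher (18 adjusted over the list alone), including the anion exchanger gene Slc4a9 (28.44 ± 1.8 against 19.97 ± 2.64 FPKM) and the proton pump gene Atp6v0d2 (15.46 ± 1.69 against 10.35 ± 1.35 FPKM). In the thick limb and distal tubule list 3 of 19 were higher (14 adjusted over the list alone), among them Slc12a3, the thiazide-sensitive cotransporter (179.4 ± 30.4 against 97.48 ± 36.1 FPKM). In the fatty acid oxidation list 10 of 42 were higher and 1 lower (12 and 1 adjusted over the list alone), with Decr2 at 25.65 ± 0.823 against 19.46 ± 2.24 FPKM. Of 46 proximal tubule genes 2 were higher and 1 lower (0 and 0 adjusted over the list alone), and Slc34a1 was at 1253 ± 420 against 1154 ± 207 FPKM (adjusted p = 0.83). Umod was at 1777 ± 397 against 1194 ± 225 FPKM (adjusted p = 0.17). No oxidative phosphorylation gene of 48 was called by limma over all genes or over the list alone. Nnmt was lower (5.848 ± 1.89 against 11.13 ± 1.62 FPKM, adjusted p = 0.032), and Nampt was at 26.01 ± 2.57 against 23.29 ± 3.61 FPKM (adjusted p = 0.28). The largest rises under the naming rule were those of an entry with gene ID 108167857 (5.616 ± 3.43 to 17.09 ± 2.97 FPKM), Hpd, an enzyme of tyrosine breakdown (2.772 ± 1.46 to 9.49 ± 4.07 FPKM), Igfbp1 (3.092 ± 1.64 to 9.775 ± 4.13 FPKM) and the unnamed locus BGI_novel_G000729 (19.93 ± 6.05 to 46.82 ± 6.6 FPKM).

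In limma, 733 entries were higher and 1076 lower in IRLacz than in IR, and 4171 had an unadjusted p under 0.05. List scores differed for 6 of 30 lists by the exact permutation test (adjusted p = 0.0397 for each, at the smallest p the design allows): collecting duct (0.609), fibroblast and matrix (-0.627), macrophage and monocyte (-0.753), M1-associated (-0.495), inflammatory mediators (-0.556) and cell cycle (-0.637). Without IRLacz replicate 1 these differences were 0.529, -0.499, -0.531, -0.333, -0.334 and -0.505, with exact permutation p from 0.0179, the smallest possible there, to 0.0357 before adjustment. After adjustment 0 of 30 lists passed there or without any other 1 library (lowest adjusted p = 0.067), and 0 passed with a mean of at least 5 FPKM. The median sign held under each scaling in all 30 lists. Camera called 20 of 30 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.38. The count of 1809 entries fell to 1089, 888 and 606 without IR replicate 1, 2 or 3, and to 1127 and 774 without IRLacz replicate 1 or 2. It was 885 with only the 2 groups in the model and 2978 with library weights. The calls of Adgre1, Il1b, Nnmt, Slc12a3, Hpd, Gpnmb, ID 108167857 and BGI_novel_G000729 were lost when some single libraries were left out, with highest adjusted p from 0.0652 for Gpnmb to 0.113 for Il1b, whose call held in 1 of 9 such settings. Lcn2 passed without IRLacz replicate 4 (adjusted p = 0.0416), and Tnf and Ccl2 without IRLacz replicate 3 (0.048 and 0.0425).

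**Figure D3:**
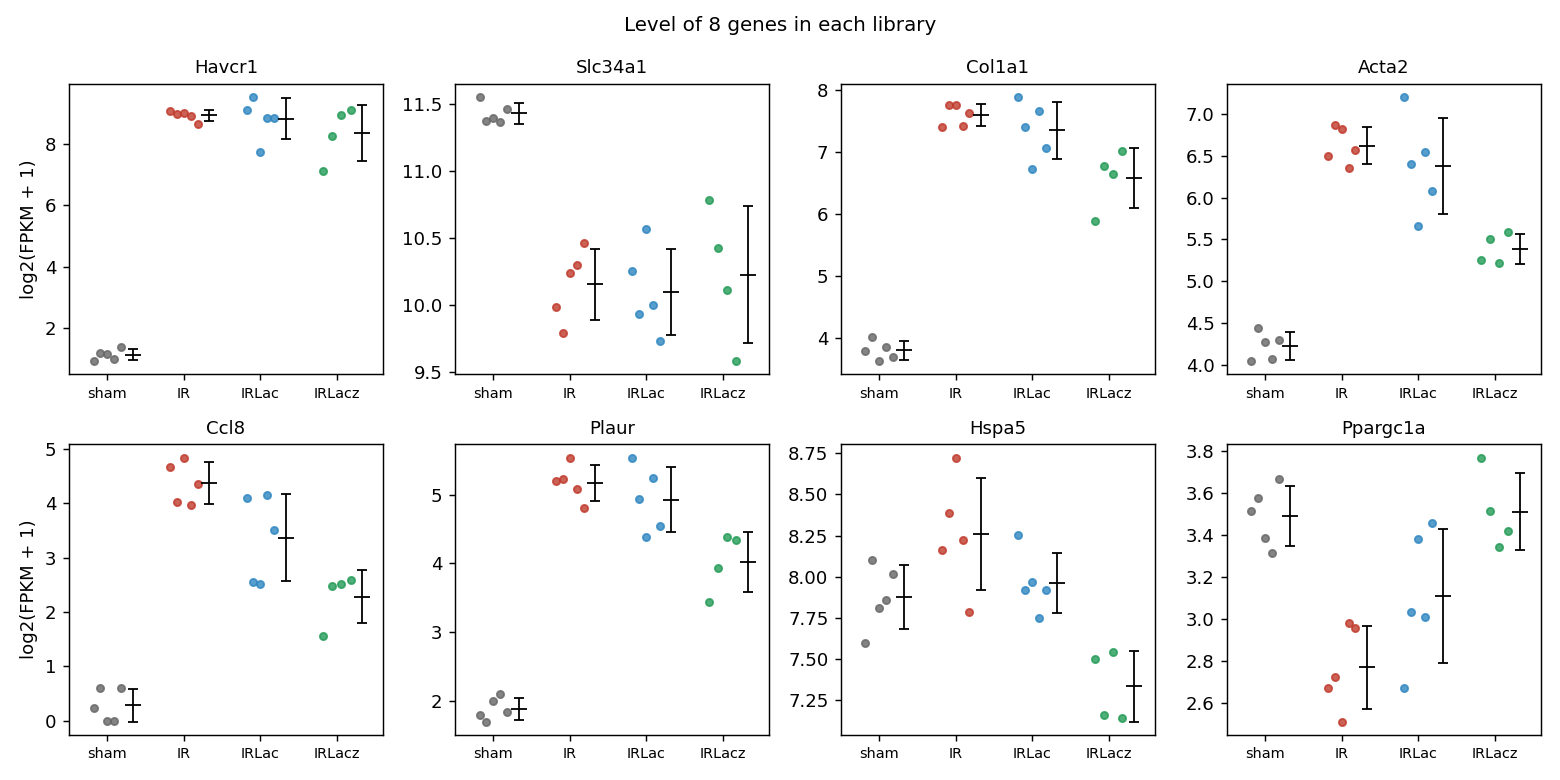
Level of 8 genes in each library as log2(FPKM + 1), by group (sham n = 5, IR n = 5, IRLac n = 5, IRLacz n = 4), with the group mean and SD as a bar beside the points. Acta2, Ccl8, Plaur and Hspa5 were lower and Ppargc1a higher in IRLacz than in IR (adjusted p from 0.0039 to 0.0063), while Havcr1 and Slc34a1 did not differ past the threshold (0.25 and 0.83).

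The comparison of IRLac with IR asked the same of the other strain, taken as Lactobacillus acidophilus. Interferon response genes were lower as a list: the median log2 difference over 39 genes was -1.12, and the list score was 3.357 ± 0.336 (SD, n = 5) in IRLac against 4.482 ± 0.786 (n = 5) in IR. Within IR the score was 3.25 in replicate 5 and 4.18 to 5.14 in the others. No gene of the list was called by limma over all genes, and 35 were lower adjusted over the list alone. The exact permutation p of the score was 0.0317 (adjusted p = 0.476), and camera's adjusted p was 4.84e-51, or adjusted p = 0.204 with an estimated correlation. The chemokine gene Ccl4 was at 1.108 ± 0.345 against 2.886 ± 0.998 FPKM, and Gbp9, a member of a family induced by interferon, at 2.626 ± 0.625 against 5.302 ± 1.44 FPKM, both with adjusted p = 0.25.

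Named injury, matrix and proximal tubule genes lay close to their IR levels in IRLac. The median was -0.114 for the tubular injury list and -0.102 for the fibroblast and matrix list. Camera called both lower with the preset correlation (adjusted p = 0.025 and 0.00115) and neither with an estimated one (adjusted p = 0.714 and 0.667). Havcr1 was at 483.6 ± 190 against 487.8 ± 53.3 FPKM, Lcn2 at 318.8 ± 101 against 386.6 ± 106 FPKM, Col1a1 at 168 ± 52 against 192.5 ± 23.2 FPKM and Slc34a1 at 1118 ± 260 against 1154 ± 207 FPKM, with adjusted p from 0.98 to 1. Il1b was at 2.094 ± 0.804 against 3.724 ± 0.481 FPKM (adjusted p = 0.28), Ppargc1a at 7.806 ± 1.89 against 5.872 ± 0.942 FPKM (adjusted p = 0.7) and Nampt at 20.06 ± 2.3 against 23.29 ± 3.61 FPKM (adjusted p = 0.86). The smallest p-values among higher genes were those of Rnf185 (16.42 ± 1.15 against 13.9 ± 0.595 FPKM), Ssc4d (1.952 ± 0.246 against 1.214 ± 0.208 FPKM) and the unnamed locus BGI_novel_G000047 (1.964 ± 1.1 against 0.132 ± 0.295 FPKM), each with adjusted p = 0.25. The red blood cell list score was lower, at 3.795 ± 0.264 against 4.621 ± 0.451 (exact permutation p = 0.00794, adjusted p = 0.238). In the urothelium list 4 of 9 genes were lower adjusted over the list alone (median -0.396, camera adjusted p = 0.000418, or adjusted p = 0.635 with an estimated correlation), with a score difference of -0.475 (exact permutation p = 0.0952).

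In limma, 0 entries were higher and 1 lower in IRLac than in IR, and 786 had an unadjusted p under 0.05. The 1 entry was the unnamed locus BGI_novel_G000424, which was listed at 0 in all 5 IRLac libraries and at 1.5, 0.93, 2.18, 1.97 and 1.62 FPKM in IR (adjusted p = 0.019). Scores differed for 0 of 30 lists after adjustment by the exact permutation test, and camera called 19 of 30 with the preset correlation and 0 with an estimated one. The count was 1 without IR replicate 2 and 0 without any of 8 other libraries. It was 116 without IR replicate 5, and Ccl4, Gbp9, Ssc4d and Rnf185 passed there, with adjusted p from 0.000881 to 0.0372. Signs differed in 3 lists: proximal tubule (median -0.00028, mean 0.0149, camera up), M2-associated (median -0.029, mean 0.0273, camera down) and fatty acid oxidation (median 0.0314, mean -0.00388, camera up).

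IRLacz and IRLac were also compared directly. Pmp22 (gene ID 18858), which encodes a myelin membrane protein also made outside nerves, was at 12.71 ± 1.21 FPKM (SD, n = 4) in IRLacz and 17.82 ± 1.76 FPKM (n = 5) in IRLac, a log2 difference of -0.46 (SE 0.076, limma adjusted p = 0.048). BGI_novel_G000424 was listed at 1.44, 2.37, 2.17 and 2.5 FPKM in IRLacz and at 0 in IRLac (adjusted p = 0.0044). Cav3, a caveolin gene named here after its values were seen, was at 1.03 ± 0.25 FPKM against 2.46 ± 0.385 FPKM (log2 difference -0.77, adjusted p = 0.019). These 3 entries, 1 higher and 2 lower, were all that limma called, and 2171 had an unadjusted p under 0.05. Adjusted over the list alone, 24 of 35 fibroblast and matrix genes and 29 of 40 cell cycle genes were lower in IRLacz, with score differences of -0.504 and -0.458 (exact permutation p = 0.0476 and 0.0397, adjusted p = 0.476 for both). The endoplasmic reticulum stress list had 9 of 21 genes lower on that count and the smallest p of these scores (-0.245, exact permutation p = 0.0159, adjusted p = 0.476), and the tubular injury list had 10 of 35 lower (-0.398, exact permutation p = 0.238). In the urothelium list, a marker of another tissue, 5 of 9 genes were higher adjusted over the list alone (median 0.798, score difference 0.787, exact permutation p = 0.0794), with IRLac below IR and IRLacz above it. Col1a1 was at 97.86 ± 29.3 against 168 ± 52 FPKM (adjusted p = 0.12), Nampt at 26.01 ± 2.57 against 20.06 ± 2.3 FPKM (adjusted p = 0.12) and Il1b at 2.198 ± 0.349 against 2.094 ± 0.804 FPKM (adjusted p = 0.85). Camera called 20 of 30 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.539, and exact tests of scores called 0. Signs differed in 3 lists: complement (median 0.00436, mean -0.0795), glycolysis (median -0.0376, mean 0.0153) and antioxidant genes (median and mean below 0, camera up). The count of 3 was 490 without IRLac replicate 3, where Col1a1 and Nampt passed (adjusted p = 0.0201 and 0.0411), between 1 and 5 without any 1 other library, and 167 with library weights. The call of Pmp22 held in 3 of 9 such settings, with adjusted p up to 0.168.

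Both treated groups were compared with sham as well. IRLacz had 7729 entries higher and 1834 lower by limma, and IRLac 7885 and 2285. With median-ratio scaling the splits were 4255 higher and 4218 lower for IRLacz, and 4580 and 4595 for IRLac, and with quantile scaling 3518 and 4215, and 4141 and 4822. Of 35 tubular injury genes 34 were higher than in sham in IRLacz and 35 in IRLac, and of 46 proximal tubule genes 38 and 39 were lower. Of 20 collecting duct genes 3 were lower and 3 higher in IRLacz, and 6 lower and 1 higher in IRLac. Of 39 interferon genes 24 were higher in IRLacz and 23 in IRLac. Camera called 20 lists in each comparison with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.152 for IRLacz and 0.178 for IRLac. Collecting duct and endoplasmic reticulum stress genes were called down by camera in IRLacz with medians of 0.0877 and 0.0801. Uncalled lists with positive medians and camera down were endothelium, glycolysis and clock genes in both comparisons, urothelium in IRLacz, and podocytes and endoplasmic reticulum stress in IRLac.

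The covariance across genes was used to set the difference between IRLacz and IR beside the injury change. With the IR libraries split so that none was shared, the covariance of the difference with the change from sham to IR was -0.158 (r = -0.625 across genes, which are not independent replicates), with splits between -0.189 and -0.11. It was -0.093 without IRLacz replicate 1. With all libraries it was -0.167, against a mean of -0.0117 in simulated unchanged groups, with most draws between -0.16 and 0.101. Of 1000 draws 22 lay at or below -0.167, and here and below such draws were counted in the observed direction only. That range holds for unsplit values with all libraries, so the split value without IRLacz replicate 1 cannot be judged by it. Whether the covariance stands apart from unchanged groups without that library was not tested. The change from -0.158 to -0.093 shows that its size rests in part on 1 library. For IRLac the split covariance was -0.0506, and 238 of 1000 simulated draws lay at or below the unsplit -0.0599. Without IRLac replicate 3 the split value was -0.00954. The responses to both strains had a split covariance of 0.0267 (r = 0.429). The unsplit one was 0.036, against 0.0127 in simulated groups that share the IR libraries, of which 54 of 1000 lay at or above 0.036. No gene was called in both comparisons with IR by limma, with 0 expected of independent lists among higher genes and 0.079 among lower ones, and 0 and 0.01 on average in simulated groups. IRLac against IR had 1 call in all, so this overlap was all but fixed in advance and says nothing about shared responses.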

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

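The tests of single libraries, of IRLacz replicate 1 and of the interferon list were chosen after the results they address had been seen.

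The first pattern is the difference between IRLacz and IR, with 1809 entries called by limma. An evenly milder injury would take every gene back toward sham by the same share of its injury change. With the position on the sham to IR line as a covariate, 101 entries were called, 64 higher and 37 lower. Of these, 48 were among the 1809. As many were called in 1 of 100 splits of the libraries, the real one included, with 38 in the highest other split. This cannot decide the question, because the line is built from the IR libraries. The position also differs between the groups, at 77% in IRLacz and 99.8% in IR. A first test of whether IRLacz replicate 1 carries the difference decided nothing, since 895 of the 1809 calls were still made in the same direction without it, close to the bound of 1 in 2. A second test, added after that one had decided nothing and after the count without replicate 1 had been seen, argues against replicate 1 carrying all of the difference: without it 1127 entries were called, 1 of 56 splits gave as many, the real one included, and the highest other split gave 498. The strain, the gavage itself, a batch that follows the groups and the authors' processing stay open. The labels give no batch, and no gavage of IR mice, with which to test them.

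The second pattern is IRLacz replicate 1, at 46% of the way from sham to IR. A mislabelled sham kidney is argued against by Havcr1, at 138.1 FPKM in this library and at most 1.64 FPKM in sham. Its relative depth was 0.985, within the 0.976 to 1.02 of the other injured libraries. Low depth stays open, because the estimate uses only values close to each gene's lowest and could miss a much shallower library. The 10 highest entries of IRLacz replicate 1 held 13.19% of the total, above the 9.004% to 11.98% of the other injured libraries. With the 18 entries that are among the 10 highest of any library left out, its position was 46.4%, below their 65.7% to 105%. This argues against a few genes taking most of the reads. A mixture of RNA from a sham and an injured kidney stays open, because 4 of 65 pairs of partner libraries gave sham shares from rising and from falling genes within 10 percentage points; all 4 had IRLac replicate 3 as the injured partner, 0 of the other 60 pairs did so (gaps of 10.9 to 27.6), and the median gap was 18.7. No biological explanation was tested for this library.

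The third pattern is the lower interferon list in IRLac than in IR, by a score difference of -1.12; IRLacz differed from IR by -1.02 (exact permutation p = 0.0873) and from IRLac by 0.103 (exact permutation p = 0.77), so the pattern is not shown to be one of IRLac alone. One IR library as the whole cause is argued against, since the difference was between -1.43 and -0.961 with each IR library left out. The IR libraries were not alike: replicate 5 scored 3.25, inside the IRLac range of 2.98 to 3.73, and the others scored 4.18 to 5.14. For an evenly milder injury, the interferon score was taken as a fraction of its own change from sham to IR, minus the position on the line as a fraction. It differed by -0.481 (exact permutation p = 0.0317). This cannot decide the question, because the fraction and the line are both built from the IR libraries. The list was also picked after its fall had been seen. Fewer macrophages and T cells in the kidney could be the source and cannot be told apart from lower expression per cell, since the score minus the mean of the macrophage and the T and NK cell scores differed by -0.774 (exact permutation p = 0.0952). The strains, the gavage itself and a level particular to these IR libraries, with which both treated groups were compared, stay open as untested. The list score itself did not pass after adjustment (exact permutation adjusted p = 0.476).

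Other splits of the libraries into groups of the same sizes were drawn, 100 for each comparison with the real one included. Chance was argued against for the counts of changed entries in IR against sham (10276, as many in 1 split, highest other 5599), IRLacz against IR (1809, in 1 split, highest other 1622), IRLacz against sham (9563, in 1 split, highest other 7270) and IRLac against sham (10170, in 1 split, highest other 7373). For IRLacz against IR the highest other split came near the real count, and a split that was not drawn could exceed it. Chance was not argued against for IRLac against IR (1 entry, as many in 12 splits, highest other 83) or IRLacz against IRLac (3 entries, in 11 splits, highest other 3164). A split with 3164 calls shows that these libraries also differ along lines other than the group, and which lines was not examined. For lists called by camera with the preset correlation, chance was argued against in none: IR against sham gave 23 (as many in 16 splits, highest other 26), IRLacz against IR 20 (35, 24), IRLac against IR 19 (26, 24), IRLacz against IRLac 20 (37, 26), IRLacz against sham 20 (31, 26) and IRLac against sham 20 (37, 25).

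A value far from the rest of its group, by the gap to its nearest neighbour as a share of the group's range, was seen in 23 of 374 sets of values, and chance gives about 19. The direct test between the treated groups called BGI_novel_G000424 (log2 difference 1.63, adjusted p = 0.0044) and Pmp22 (-0.456, adjusted p = 0.048). In IRLac replicate 3 the position was 67% against 93.3% to 101% in the others (share of the range 0.774), the proximal tubule score 7.47 (0.756) and the tubular injury score 5.59 (0.739), and the levels were 4.32 FPKM for Dpys (0.772), 178 for Idh3g (0.769) and 242 for Sdhc (0.741). In IRLac replicate 1 the endoplasmic reticulum stress score was 5.38 (0.819). In IRLacz replicate 1 the levels were 1.93 FPKM for Ccl8 (0.856) and 2.99 for Plk1 (0.899), and in IRLacz replicate 3 Ccl7 was at 6.11 FPKM (0.836) and the glycolysis score at 5.87 (0.993). In IR replicate 1 BGI_novel_G000047 was at 0.66 FPKM, with 0 in the others (share 1), and Serpina10 at 102 FPKM (0.76). In IR replicate 3 Gpnmb was at 28.6 FPKM (0.716). In IR replicate 5 Pvalb was at 6.17 FPKM (0.793), Serpina1d at 23.5 FPKM (0.876) and Slc22a7 at 32.3 FPKM (0.778). Among sham libraries, Tnf was at 0.38 FPKM in replicate 2 (0.862), Bst2 at 35.5 FPKM in replicate 3 (0.762) and Ccl7 at 0.84 FPKM in replicate 5 (0.794). The sham scores were 1.06 for the cell cycle (0.792) and 8.49 for ribosomal proteins (0.712) in replicate 3, and 3.96 for immediate early and heat shock genes (0.963) in replicate 4.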

How the results depend on the processing

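Leaving out the 2 injured libraries nearest to sham, and the position as a covariate, were chosen after seeing the data. Of 1319 comparisons of single genes and list scores with another setting, 1268 kept their direction and their side of the threshold, 37 lost the call, 10 gained it and 4 changed sign. With 1 library left out, 939 of 1018 kept both. These totals pool the contrasts and include genes that were never called. In IRLacz against IR, 11 of the 30 called named genes lost the call in at least 1 other setting, and 9 with 1 library left out. In IR against sham 0 of 33 did so in either case. The cause of the changes below was not tested. The count for IRLacz against IR (1809) was 885 with only the 2 groups, 2978 with array weights, 101 with the position as a covariate (48 shared) and 606 to 2197 with 1 library left out; 1626 were called without the 2 nearest libraries, 1225 of them shared. For IRLac against IR (1) it was 0 with a mean of at least 5 FPKM, with array weights, with the replicate block and without the 2 nearest libraries, and 0 to 116 with 1 library left out. For IRLacz against IRLac (3) it was 1 with a pseudocount of 0.1 or 0.01, with only the 2 groups, with the replicate block and with the covariate, 5 with no filter, 0 with a mean of at least 5 FPKM, 167 with array weights, 86 without the 2 nearest libraries and 1 to 490 with 1 left out. With an estimated inter-gene correlation 0 lists were called by camera in all 6 comparisons. The 6 list scores that passed in IRLacz against IR became 0 with a mean of at least 5 FPKM, 0 without the 2 nearest libraries and 0 to 0 with 1 library left out, where fewer libraries raise the smallest possible p. The injury profile covariance of IRLacz (-0.158) was -0.3 with a pseudocount of 0.01, -0.115 with no filter, -0.185 as TPM, -0.093 without the 2 nearest libraries and -0.202 to -0.093 with 1 left out. That of IRLac (-0.0506) was -0.103 with a pseudocount of 0.01, -0.00954 without the 2 nearest and -0.0799 to -0.00954 with 1 left out, and the covariance of both responses (0.0267) was 0.0415, 0.015 and 0.0151 to 0.0431. Differences that changed sign, none of them called, were Havcr1 in IRLac against IR (0.0708 with array weights, 0.157 without the 2 nearest, -0.294 to 0.157 with 1 left out), Umod there (-0.039 without the 2 nearest, -0.039 to 0.398), Slc34a1 there (-0.174 to 0.034) and in IRLacz against IR (-0.112 without the 2 nearest, -0.112 to 0.287), and, in IRLacz against IRLac, Slc34a1 (-0.0554 to 0.344), Il1b (-0.0219 to 0.204) and the interferon score (-0.0957 to 0.393). Same-numbered libraries of different groups had a median correlation of -0.0668 over 27 pairs, and 3 of 19 libraries correlated best with their own number, so the numbers were not read as pairs; with the replicate number as a block, 1574 entries were called in IRLacz against IR. Depth is known only relative to other libraries, so no counting error is given for low values.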

Other observations

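The transcription factor families were examined after the comparisons above had been seen. Of 666 tested transcription factors with at least 95 percent identity to their database match, 424 were higher and 59 lower in IR than in sham by limma. Over all 13594 entries the counts were 7747 and 2529. Whether transcription factors differ from other entries was not tested. Sox9 rose from 0.248 ± 0.0719 to 9.51 ± 1.58 FPKM and Spi1 from 4.4 ± 0.536 to 37.8 ± 5.74 FPKM, while Esrrb fell from 13.1 ± 2.34 to 3.35 ± 1.1 FPKM and Lhx1 from 9.09 ± 0.327 to 3.98 ± 1 FPKM. In IRLacz against IR 31 were higher and 53 lower, beside 733 and 1076 of all 13594 entries, and in IRLac against IR 0 and 0. Esrrg was higher in IRLacz (12.9 ± 0.513 against 7.51 ± 1.43 FPKM, limma adjusted p = 0.0061), as were Esrrb (7.64 ± 3.35 against 3.35 ± 1.1 FPKM, 0.042) and Lhx1 (5.9 ± 0.749 against 3.98 ± 1 FPKM, 0.017). Foxs1 (2.55 ± 0.546 against 6.74 ± 1.13 FPKM, adjusted p = 0.0017) and Myc (15.2 ± 4.83 against 27.4 ± 6.06 FPKM, 0.032) were lower. Of 38 bZIP factors 11 were lower in IRLacz (camera adjusted p = 0.00472, or adjusted p = 0.744 with an estimated correlation).

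Col19a1 was among the 4 highest entries of each group, at 13190 ± 317 FPKM in sham, 7321 ± 453 in IR, 8441 ± 1580 in IRLac and 9065 ± 2850 in IRLacz. It was lower in IR than in sham, while the collagen genes Col1a1 and Col3a1 were higher. Whether its reads come from this gene was not tested, so its level is uncertain.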
